A study of Mus musculus with 6 samples.

How the data were processed

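Open chromatin was profiled by ATAC-seq, in which a hyperactive Tn5 transposase inserts sequencing adapters into accessible DNA. The tissues were the posterior second heart field (pSHF), the progenitor field dorsal to the heart that feeds the venous pole, and the atria of the embryonic heart (HT). Per the labels, both were dissected from wild-type embryos of the outbred CD1 strain at embryonic day 10, pooled, dissociated and transposed, and each tissue has 3 samples.

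Per the submitters' processing notes, the tools were Bowtie2 2.3.2, SAMtools 1.5, Picard and MACS2 2.1.1, and the genome build was mm10. Their roles, order and parameters are not given in the sources used here. The deposited data analysed here are 1 peak list per tissue, so each value below belongs to the authors' list of that tissue and not to a replicate. Whether the 3 samples were pooled before peak calling is not given in the sources used here. No value per replicate was at hand, so no SD, no test between tissues and no p-value is given, and no difference could be set against the spread between replicates.

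Each line of a list is a summit with its position and 4 values from the authors' peak caller. These are a score, the fold enrichment over the caller's background as a ratio, the −log10 p-value and the −log10 q-value. The deposited score equalled 10 times the −log10 q-value to within 1 unit in 100% of pSHF lines and 99.995% of HT lines. The lowest deposited −log10 q was 1.3013 in pSHF and 1.30685 in HT, just above the 1.30103 that a q threshold of 0.05 gives. The HT list held 60223 lines and the pSHF list 58887. Lines with the same start and end were taken as summits of 1 peak, and the summit with the highest fold enrichment was kept. This left 49267 HT peaks and 44018 pSHF peaks on 20 chromosomes (the 19 autosomes and X), with no overlap between peaks of 1 list.

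Read totals were not in the files, but coverage was recovered from the deposited fold enrichment and −log10 p. Fold values recurred in steps of 0.548 in HT and 0.539 in pSHF. Such steps arise if fold enrichment is (pileup + 1)/(background + 1) with a whole-number pileup. On that formula the genome-wide background pileup was 0.824 reads per position in HT and 0.857 in pSHF, a pSHF-to-HT ratio of 1.04. With a background at or above that value, a whole pileup matched the Poisson p within 0.01 on the log10 scale at 100% of summits in both lists. The median summit pileup was 14 reads in HT and 13 in pSHF, and the smallest was 5 in both. The background reflects reads times the length to which the caller extended them, so it gives total coverage and not the number of reads.

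A peak was called shared if it overlapped a peak of the other list by at least 1 bp, and restricted otherwise. Restricted therefore means absent from the other list at its threshold, not closed chromatin. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Chance overlap was measured by moving all pSHF peaks along their chromosomes by 1 to 10 Mb in 10 steps.

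Genes came from a RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10. It gave gene starts and ends without strand, exons or sequence. For that reason parts of the plan changed. Peaks near a transcription start site became peaks with a summit within 1 kb of either gene end. Peaks went to the nearest protein-coding gene body (distance 0 inside a gene) within 100 kb instead of the nearest start site. Exons and introns were not separated. The comparison of transcription factor motifs was not run, because no genome sequence was used here. The nearest gene is a label of position and need not be the gene that an element regulates.

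For each of 21631 protein-coding genes, restricted peaks were counted and the balance log2((pSHF-restricted + 1)/(HT-restricted + 1)) was computed. 19 gene lists with 251 symbols, all found in the gene table, were fixed before the data were examined. 16 of the symbols stood in more than 1 list. They covered the Hedgehog pathway, second heart field progenitors, cardiac transcription factors, sarcomere, cardiac ion handling, atrial identity, anterior Hox genes, retinoic acid and Wnt signaling, cell cycle, housekeeping, and markers of other cell types that a dissected piece could hold. The mean balance of a list was ranked among 10000 random lists of the same size, matched on the number of peaks per gene. A list was said to lean to a tissue below percentile 2.5 or above 97.5. Of 19 lists, 0.95 would do so by chance. The percentiles describe these 2 peak lists and are not tests across embryos. Neighbouring genes such as Hox or globin clusters share their surroundings, which scattered random lists do not, so their percentiles can be too extreme.

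The genes named were set by a rule fixed before the data were examined. They were the 10 genes with the largest excess of restricted peaks each way, the 3 with the largest excess in each list that leaned, 14 genes chosen in advance, and the strongest peaks. Windows of 100 kb were ranked by the difference in restricted peaks. Some genes and windows that the rule takes are not reported here. Other genes named below were chosen after their values were seen. Alternatives covered the q threshold, equal list lengths, the overlap rule, stronger restricted peaks, distances, the pseudocount and the list statistic. The q threshold was applied to both lists before they were compared, so a peak whose partner fell below it counts as restricted. Stronger restricted peaks were those at or above their own list's median fold enrichment, 4.85 in pSHF and 5.49 in HT. Lists and gene families added after seeing the data are named as such.

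The overlap function gave the same counts as bedtools 2.31.1 on simulated intervals. The list ranking was tested on simulated data with the real 21631 genes and lists of 15 genes. It called 69.5% of 200 lists whose odds of a pSHF peak were raised 3 times, 59.5% of 200 whose odds were lowered as much, and 4% of 200 unchanged lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.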

Results

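Accessible chromatin was compared between the pSHF and the atria of mouse embryos at embryonic day 10, in a study of Hedgehog-dependent gene networks and the timing of differentiation. The comparison asks which sites are open in progenitors that have not yet joined the heart, in the differentiated atria, or in both. Each tissue had 3 samples and 1 peak list. The pSHF list held 44018 peaks covering 14.6 Mb with a median width of 251 bp, and the HT list held 49267 peaks covering 15.8 Mb with a median width of 233 bp. Coverage was close in both, with a background pileup of 0.857 reads in pSHF and 0.824 in HT.

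About 2 in 3 pSHF peaks were also peaks in the atria, and a higher share of these common sites than of restricted sites lay near gene ends. Of the pSHF peaks, 28886 (65.6%, 95% interval 65.2 to 66.1) overlapped an HT peak and 15132 (34.4%, 33.9 to 34.8) did not. Of the HT peaks, 26867 (54.5%, 54.1 to 55.0) overlapped a pSHF peak and 22400 (45.5%, 45.0 to 45.9) did not. When the pSHF peaks were moved along their chromosomes, a median of 1.34% overlapped an HT peak (range 1.27 to 1.55 over 10 shifts). Within 1 kb of a gene end lay 53.9% of shared pSHF peaks (53.4 to 54.5) and 52.5% of shared HT peaks (51.9 to 53.1). The share was 17.5% for pSHF-restricted peaks (16.9 to 18.2) and 14.4% for HT-restricted peaks (13.9 to 14.8), against a median of 6.72% for the moved peaks. More than 1 kb from any gene end, 48.6% of pSHF-restricted and 54.3% of HT-restricted peaks lay inside a gene, and 33.9% and 31.3% lay between genes. The rule for overlap changed these counts, since a 50% reciprocal overlap gave 24034 pSHF-restricted peaks.

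Restricted peaks were weaker and narrower than shared peaks in both tissues. In the pSHF list the median fold enrichment, as given by the authors' peak caller, was 4.31 in restricted peaks (quartiles 3.77 and 4.85) and 5.54 in shared peaks (4.39 and 7.54). In the HT list it was 4.84 (4.02 and 5.95) and 7.0 (4.97 and 10.1). Median widths were 164 and 329 bp in pSHF and 173 and 351 bp in HT. Among the 5000 peaks of highest fold enrichment in each list, 49 were restricted in pSHF (0.98%, 0.726 to 1.29) and 313 in HT (6.26%, 5.60 to 6.97). Drawing the same HT sites again with Poisson counting error and equal signal would leave 8.95% of HT peaks below the pSHF threshold, and the reverse draw would leave 11.6% of pSHF peaks below the HT threshold. With the signal scaled by the median pSHF-to-HT pileup ratio of 0.8 at 22806 paired shared peaks, or by 1.25 for the reverse draw, these shares were 18.4% and 4.43%, below the observed 45.5% and 34.4%. These draws leave out variation between samples, which 1 list per tissue does not give. They also take the observed pileup of each called peak as its true signal. Called peaks are those that passed the threshold, so the draws can understate the share lost to counting error. The ratio of 0.8 comes only from pairs called in both lists.

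**Figure D1:**
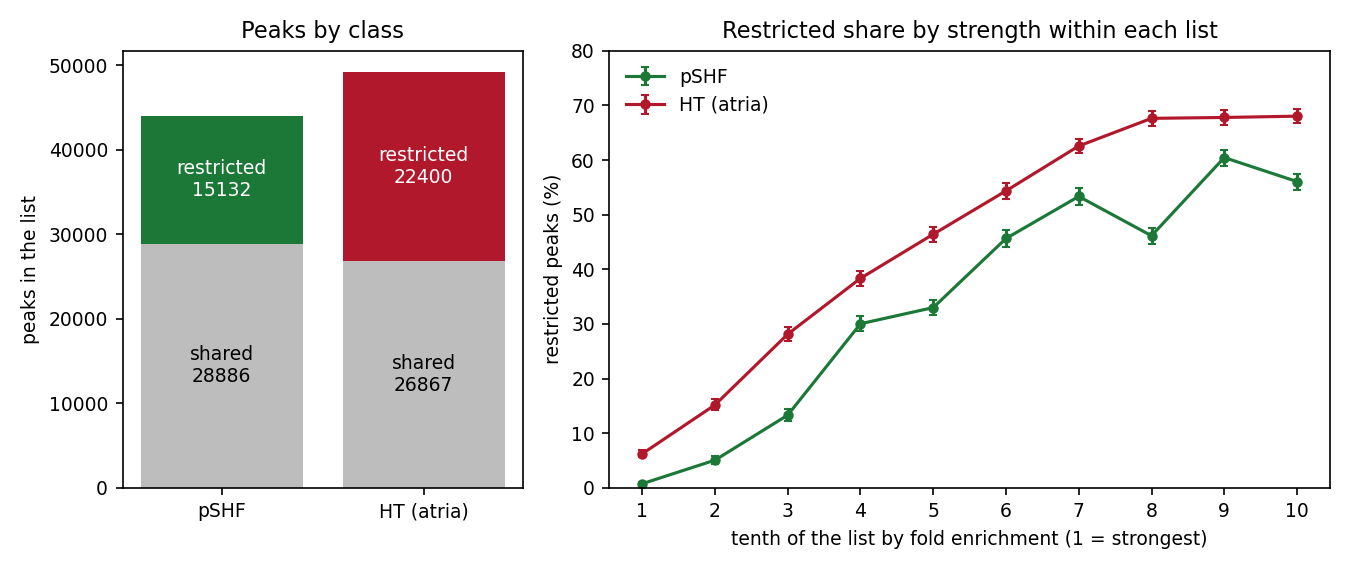
Left, number of peaks per list, split into peaks shared with the other list (grey) and restricted peaks (colour); right, percent of restricted peaks in 10 equal groups of each list ordered by fold enrichment, with exact 95% intervals for counting error. The restricted share is 0.75% in the strongest group and 56.1% in the weakest for pSHF, and 6.23% and 68.0% for HT. In pSHF it does not rise steadily, with 46.1% in group 8 and its highest value, 60.4%, in group 9.

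Genes of second heart field progenitors carried more restricted peaks in the pSHF than in the atria. Over the 16 genes of the list, 37 pSHF-restricted and 17 HT-restricted peaks lay nearest a member. The mean balance was 0.71 on the log2 scale (median 0.58), at percentile 100 of the random lists. More pSHF-restricted peaks were found at 10 genes, more HT-restricted peaks at none, and equal numbers at 6. *Foxf1*, a forkhead factor of the pSHF and splanchnic mesoderm (chromosome 8, 121084386 to 121088154), had 7 pSHF-restricted peaks and 1 HT-restricted peak, a difference of 6 that was 1 at a −log10 q of at least 5, 1 at or above the median fold enrichment, 3 without peaks near gene ends and 11 within 500 kb. *Osr1*, an atrial septum progenitor factor, had 1 and 0. *Isl1*, the LIM homeobox marker of the second heart field, had 2 of each (8 more in pSHF within 500 kb) and shared its strongest pSHF peak, at chromosome 13, 116309317 to 116309962, with the atria. Foregut endoderm and somite markers leaned the same way (percentiles 99.7 and 99.96). When restricted peaks were kept only at or above their list's median fold enrichment, the percentile was 95.7 and the list no longer stood apart. At a −log10 q of at least 5 its mean turned to -0.08. That was still at percentile 99.2, because the random lists lay further toward the atria. Peaks whose partner in the other list fell below the cutoff count as restricted there.

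Hedgehog pathway genes also leaned to the pSHF, with 57 pSHF-restricted and 31 HT-restricted peaks over 12 genes (mean balance 0.40, median 0.29, percentile 99.5). More pSHF-restricted peaks were found at 6 genes and more HT-restricted peaks at 5. *Gas1*, which encodes a co-receptor for Hedgehog ligands (chromosome 13, 60174405 to 60177535), had 11 pSHF-restricted peaks and none restricted to the atria, a difference that was 3 at a −log10 q of at least 5, 3 at or above the median fold enrichment and 5 within 50 kb. The transcriptional effectors *Gli2* and *Gli3* had 14 and 7, and 11 and 4, pSHF-restricted and HT-restricted peaks. The co-receptor genes *Boc* and *Cdon* had 6 and 2, and 5 and 3. Among transcriptional targets of the pathway, *Hhip* had 3 and 1, *Gli1* had 1 of each, and *Ptch1*, the receptor gene, had 1 pSHF-restricted and 2 HT-restricted peaks. Without *Gas1* the mean was 0.11, percentile 94.6, so the call rested on that gene, and it also ended within 500 kb (96.9) and at or above the median fold enrichment (96.6). At a −log10 q of at least 5 the mean turned to -0.08, percentile 99.8, and *Gli2* had 1 more HT-restricted than pSHF-restricted peak. Here too, peaks whose partner fell below the cutoff count as restricted. *Gli3* had equal numbers at or above the median fold enrichment.

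**Figure D2:**
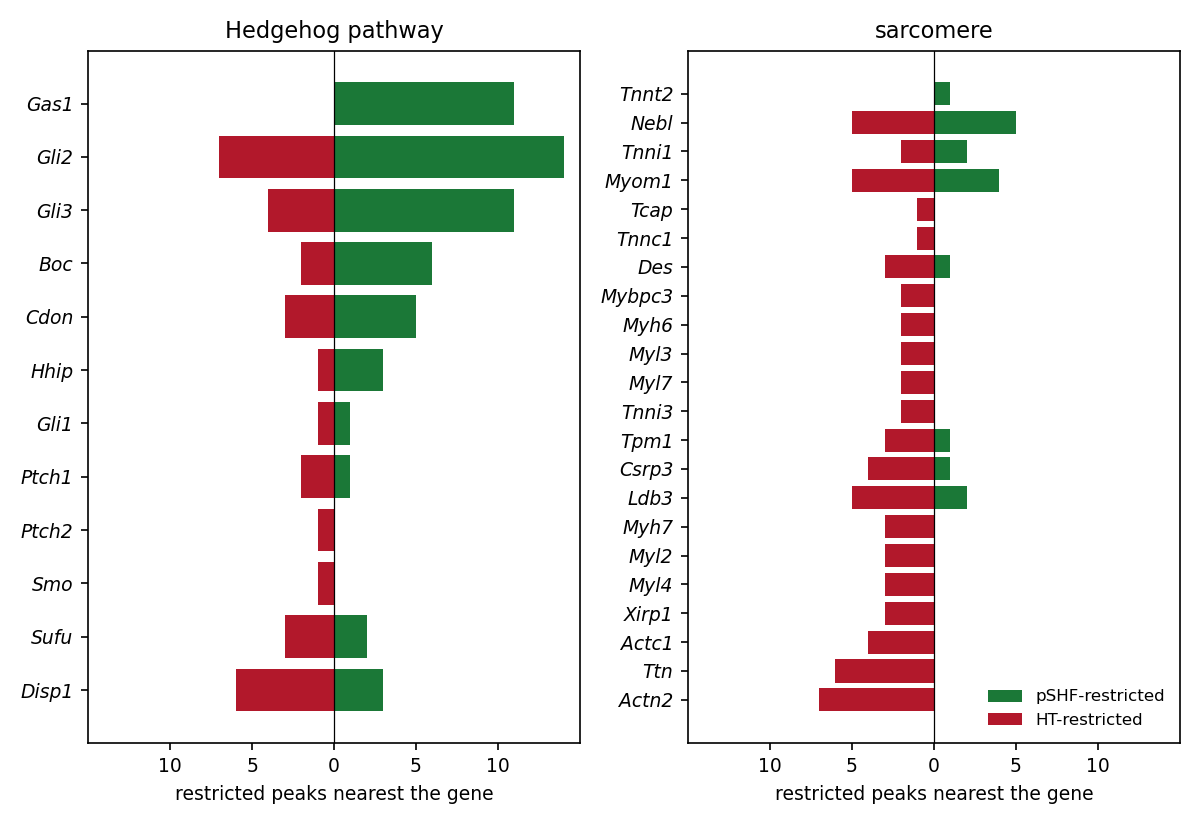
Number of restricted peaks whose nearest protein-coding gene is the gene named, for the Hedgehog pathway and sarcomere lists (pSHF-restricted to the right, HT-restricted to the left). *Gli2* reaches furthest to the right with 14 pSHF-restricted peaks, *Gas1* has 11 and no HT-restricted peak, and *Actn2* and *Ttn* reach to the left with 7 and 6 HT-restricted peaks.

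Genes of patterning and mesenchymal identity leaned the same way. The anterior Hox genes had 22 pSHF-restricted and 7 HT-restricted peaks over 15 genes (mean 0.62, percentile 99.99), with 8 genes in excess in pSHF and 1 in HT. *Hoxc4* had 4 and 1, and *Hoxb3* had 3 and 1. The visceral mesenchyme list had 36 and 20 over 12 genes (mean 0.56, percentile 99.9), among them *Six2* with 7 and 2 and *Barx1*, a stomach mesenchyme factor, with 5 and 1. The pSHF was ahead at 8 genes and the atria at 2, *Hlx* with 0 and 5 and *Tcf21* with 1 and 4. This list shares *Foxf1*, *Foxf2*, *Wnt2* and *Fgf10* with the progenitor list and *Nkx3-2* with the somite list. The progenitor list also shares *Aldh1a2* with the retinoic acid list and *Wnt2* with the Wnt list, and 2 of the anterior Hox genes stood in another list. Retinoic acid genes had 33 and 24 (mean 0.32, median 0, percentile 99.4). The receptor genes *Rarg* and *Rarb* had 3 and 0, and 9 and 6, and *Aldh1a1*, a retinoic acid synthesis enzyme, had 2 and 0. Wnt pathway genes had 27 and 22 (mean 0.24, median 0, percentile 98.4), with 4 and 1 at *Wnt11*, 4 and 2 at *Lgr5* and 2 and 0 at *Rspo3*. At or above the median fold enrichment, the anterior Hox and visceral mesenchyme lists were the ones still leaning to the pSHF (percentiles 99.8 and 98.0), and at a −log10 q of at least 5 the visceral list lay at 97.2. By the median instead of the mean, the retinoic acid and Wnt lists did not stand apart (percentiles 66.4 and 78.4), and without *Wnt11* the Wnt percentile was 95.8. The Wnt list also fell within the bounds at a −log10 q of at least 5 (82.2), with reciprocal overlap (97.1) and by pooled share (96.9), and the retinoic acid list with reciprocal overlap (96.8). At a −log10 q of at least 5 the excess at *Hoxb3*, *Rarb* and *Lgr5* was on the HT side. At *Hoxb3* this came from a shared HT peak (−log10 q 5.75) whose pSHF partner (2.57) fell below the cutoff. The 1 HT-restricted peak of *Hoxb3*, at 2.01, did not pass it.

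Sarcomere genes carried their restricted peaks in the atria. Of 85 restricted peaks nearest one of the 22 genes, 68 were HT-restricted and 17 pSHF-restricted, a mean balance of -1.35 (median -1.58) at percentile 0 of the random lists. The atria had the larger number at 19 genes, the pSHF at 1 (*Tnnt2*, with 1 and 0), and 2 were equal. *Actn2*, encoding the Z-disc protein alpha-actinin 2 (chromosome 13, 12269426 to 12340732), had 7 HT-restricted and 0 pSHF-restricted peaks, beside 2 shared peaks. *Ttn*, encoding titin, had 6 HT-restricted peaks and no peak in the pSHF list, and its strongest, at chromosome 2, 76982438 to 76982709, lay across an end of the gene. *Actc1*, cardiac alpha-actin, had 4 and 0. *Myl7*, the atrial myosin light chain, had 2 HT-restricted peaks and 1 shared peak. Erythroid markers leaned to the atria too (percentile 0). The sarcomere list stood below percentile 2.5 under every alternative run.

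Other cardiac lists lay on the same side without passing the bound. Cardiac transcription factor genes had 68 HT-restricted and 29 pSHF-restricted peaks (mean -0.89, percentile 3.0), with the atria ahead at 15 of 19 genes. Ion handling genes had 71 and 33 (mean -0.88, percentile 2.54) and atrial identity genes 34 and 16 (mean -0.68, percentile 10.8). *Nkx2-5*, a core cardiac homeobox gene, had 3 HT-restricted peaks and no peak in the pSHF list. *Gata4* had 5 HT-restricted and 2 pSHF-restricted peaks, and *Tbx5* had 6 and 4. *Nppa*, encoding atrial natriuretic peptide, had a single peak, in the atria alone, at chromosome 4, 148000164 to 148000740, across an end of the gene. *Hcn4*, the pacemaker channel gene, had 2 HT-restricted and 0 pSHF-restricted peaks. *Myocd*, a serum response factor coactivator chosen after its values were seen, had 10 HT-restricted and 0 pSHF-restricted peaks, beside 3 shared pSHF peaks. Among peaks at or above the median fold enrichment of each list, *Gata4* had 2 more restricted peaks in pSHF. The cutoff was 4.85 in pSHF and 5.490 in HT, which the strongest HT-restricted peak of *Gata4*, at 5.482, just missed. The ion handling list passed the bound under 7 alternatives, the transcription factor list under 3 and the atrial list under 1, with percentiles down to 0.14, 0.63 and 1.36.

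**Figure D3:**
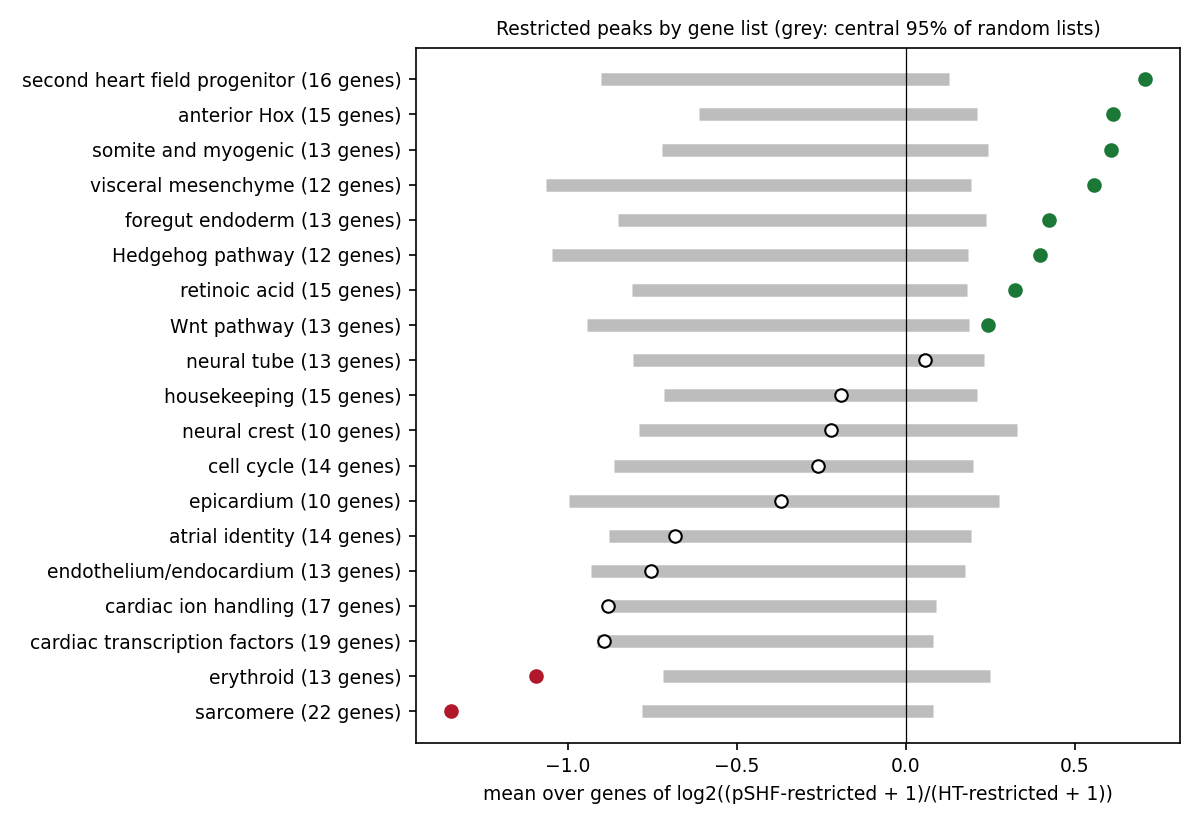
Mean balance of restricted peaks per gene list (points) against the central 95% of 10000 matched random lists (grey bars); the horizontal axis is log2, positive toward the pSHF. Of the 19 lists, 8 lean to the pSHF (green) and 2 to the atria (red).

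Markers of other cell types differed between the pieces as well. Foregut endoderm genes leaned to the pSHF with 27 and 17 restricted peaks (mean 0.42, percentile 99.7). *Grhl2* had 5 and 2, and *Foxa2*, the endodermal forkhead gene, had 6 and 4, a difference of 2 that was 0 at a −log10 q of at least 5 and 9 within 500 kb. Somite and myogenic genes leaned the same way with 21 and 9 (mean 0.61, percentile 99.96), with 3 and 0 at *Uncx*, 2 and 0 at *Meox2* and 4 and 2 at *Pax1*. Erythroid genes leaned to the atria with 23 HT-restricted and 4 pSHF-restricted peaks (mean -1.10, percentile 0). *Hbb-y* had 4 and 0, *Gata1* 3 and 0 and *Hbb-bh1* 2 and 0. With peaks near gene ends left out, the erythroid percentile was 4.19, and by the median it was 3.75. The endoderm percentile was 87.7 at a −log10 q of at least 5, and at or above the median fold enrichment the endoderm and somite percentiles were 96.0 and 94.3. Endothelial and endocardial genes had 48 HT-restricted and 25 pSHF-restricted peaks (percentile 9.08, or 0.16 at a −log10 q of at least 5), including 6 and 2 at *Cdh5*. At or above the median fold enrichment of each list, *Cdh5* had 1 more in pSHF. This cutoff kept a pSHF-restricted peak of 4.85 but not the strongest HT-restricted peak of 5.26, because it was 5.49 in HT. The epicardial list lay at percentile 50.9, with 4 HT-restricted peaks and 1 pSHF-restricted peak at *Wt1*. The neural tube (90.0), neural crest (52.8), cell cycle (62.3) and housekeeping (61.0) lists lay within the bounds, although the neural tube list passed them by the nearest gene end (97.7).

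Across the genome, 10948 of 21631 protein-coding genes had a restricted peak assigned. The pSHF had more at 3233 and the atria at 6333, and of the assigned restricted peaks 39.3% were pSHF-restricted. The largest pSHF excess was at *Lrmda* on chromosome 14, with 33 pSHF-restricted and 4 HT-restricted peaks over 1037 kb. It was followed by *Asic2* with 16 and 4, *Gas1*, and *Pappa* with 13 and 2. Next were *Unc5c*, a netrin receptor gene, with 13 and 3, and *St6gal1* with 9 and 0. An excess of 8 was found at *Errfi1*, *Pdgfc*, *Skap1* and *Cadm1*, among other genes. The largest HT excess was at *Macrod2*, a gene of 1998 kb, with 25 HT-restricted and 8 pSHF-restricted peaks. The protein kinase C genes *Prkca* and *Prkce* had 17 and 3, and 15 and 1. *Gse1* had 22 and 8, *Mc3r* and *Spock1* 13 and 1 each, *Chd7*, a chromatin remodeller gene, 16 and 4, *Zmiz1* 18 and 6, *Grb10* 12 and 1, and *Cdh13* 16 and 5. The order depended on the assignment of peaks inside long genes: by nearest gene end the pSHF minus HT difference was 7 at *Lrmda* (from 29) and 3 at *Asic2* (from 12), and it was -2 at *Macrod2* (from -17) and *Prkce* (from -14), -1 at *Spock1* (from -12), -4 at *Cdh13* (from -11) and -5 at *Gse1* (from -14), while *Mc3r* and *Chd7* stayed at -12. At a −log10 q of at least 5 it was 3 at *Lrmda* and *Gas1*, 1 at *Asic2* and 5 at *Errfi1*, and at or above the median fold enrichment it was 5 at *Lrmda*, 3 at *Gas1* and 0 at *Chd7*.

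The window with the largest excess of HT-restricted peaks held the beta-globin genes. Of 15333 windows of 100 kb with a restricted peak, 4915 held more from pSHF and 8251 more from HT. The window with the largest pSHF excess, chromosome 17, 83100001 to 83200000, had 10 and 1 restricted peaks, and the nearest gene within 100 kb, where there was one, was *Pkdcc*. It was followed by a window at *Gas1* (chromosome 13, 60200001 to 60300000) with 8 and 1. A window at *Errfi1* and *Slc45a1* on chromosome 4 had 7 and 0, and one on chromosome 1 from 90400001 to 90500000 had 6 and 0 and no gene within reach. In the atria the first window was chromosome 7, 103800001 to 103900000, which spans *Hbb-bt*, *Hbb-bs*, *Hbb-bh1* and *Hbb-y*, with 13 HT-restricted and 0 pSHF-restricted peaks, beside 2 shared pSHF peaks. The next held *Mc3r* (13 and 1), *Emilin2* and *Lpin2* (11 and 0), a histone gene cluster on chromosome 13 (10 and 0) and a ribonuclease and angiogenin cluster on chromosome 14 (9 and 0). The histone window held 29 HT peaks in all and 19 pSHF peaks, all of the latter shared.

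**Figure D4:**
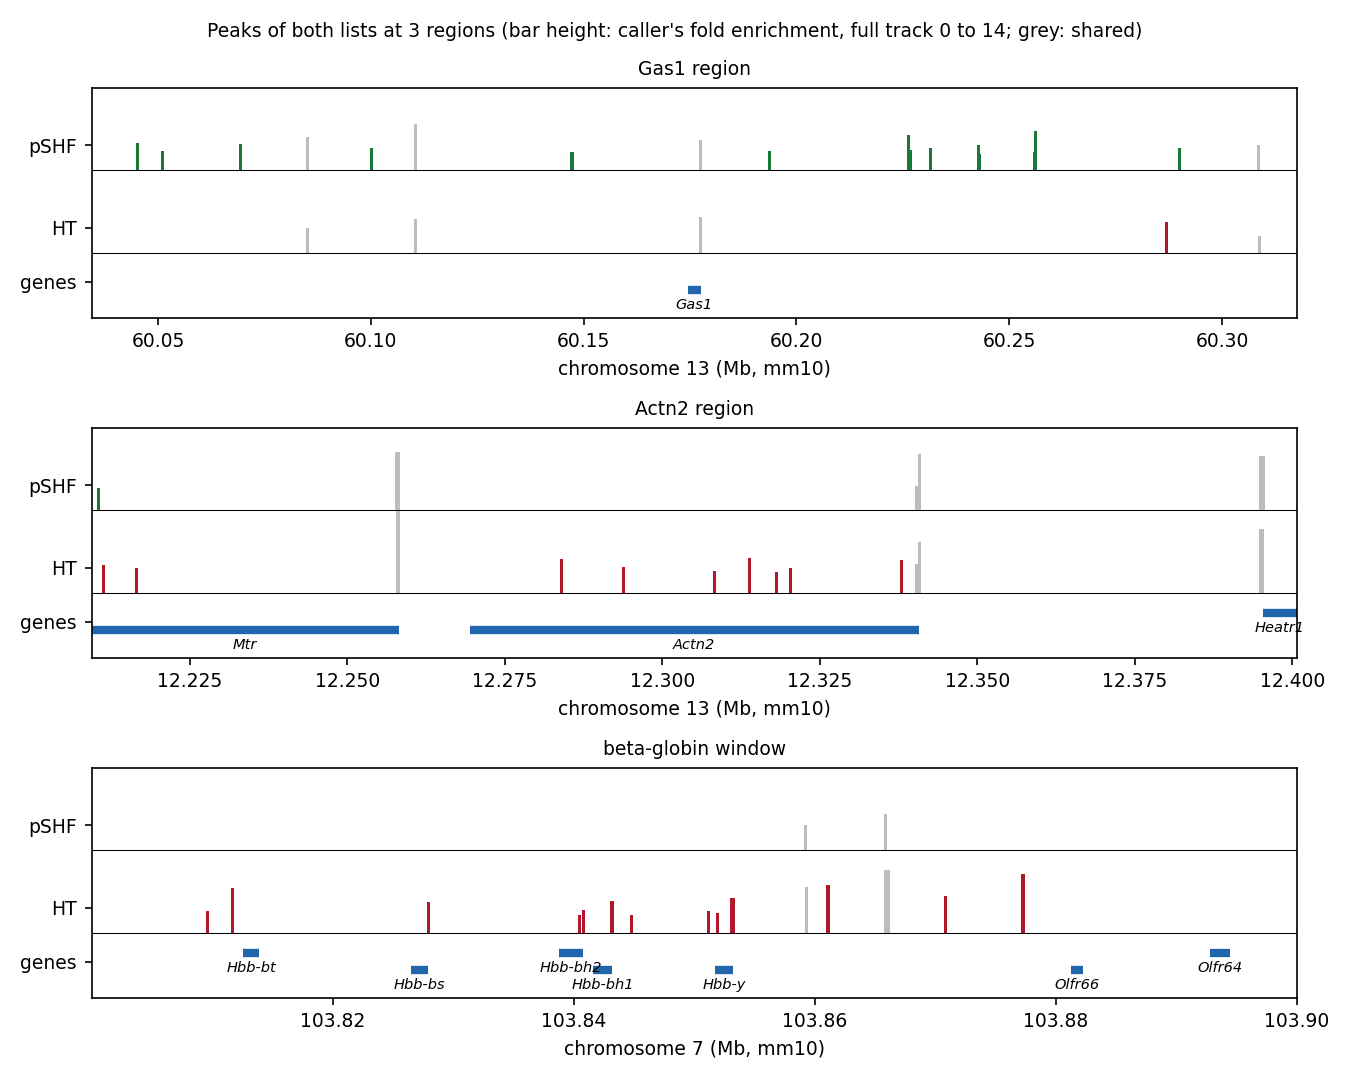
Peaks of both lists at *Gas1*, *Actn2* and the beta-globin window on mm10; bar height is the caller's fold enrichment, colour marks restricted and grey shared peaks, narrow peaks are widened to be visible, and blue bars are protein-coding genes. The *Gas1* map holds 15 pSHF-restricted peaks against 1 in HT, the *Actn2* map 9 HT-restricted against 1 in pSHF, and the globin map 13 HT-restricted against 0.

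The strongest HT-restricted peak, at chromosome 4, 148204035 to 148204340, had a fold enrichment of 19.0 and a −log10 q of 50.9. It lay 3878 bp from the nearest end of any gene, coding or not, and its nearest protein-coding gene was *Disp3*. The strongest pSHF-restricted peak, at chromosome 8, 63755161 to 63755648, reached 13.3 with a −log10 q of 26.5, inside the predicted gene *Gm35424* and with no protein-coding gene within 100 kb. The strongest shared peak of the pSHF list, at chromosome 3, 5860518 to 5860863, had a fold enrichment of 23.2 and lay 109361 bp from the nearest gene end. In the HT list the strongest shared peak, at chromosome 1, 24613004 to 24613230 near *Col19a1*, reached 30.2. Regions prone to mapping artifacts were not filtered out here, so the strongest peaks may include such signal.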

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

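No paired analysis was possible because each tissue has 1 peak list with no value per replicate, and for the same reason no replicate could be left out. The motif alternatives were not run. The settings by nearest gene end, by the median and without a list's largest gene were chosen after seeing the data. Requiring a −log10 q of at least 5 in both lists before comparing them gave 4204 pSHF-restricted and 14206 HT-restricted peaks. Shared peaks numbered 16270 in pSHF and 15597 in HT. The restricted counts include peaks that are shared in the full lists, because their partner fell below the cutoff. By construction, restricted peaks at or above the median fold fell to 4357 and 6631, and a 50% reciprocal overlap raised the pSHF count to 24034. The percent near a gene end in pSHF-restricted, HT-restricted, shared pSHF and shared HT peaks was 23.9, 18.0, 69.1 and 68.5 at the stricter q, 28.4, 20.2, 57.2 and 57.1 with reciprocal overlap, and 28.1, 18.6, 51.2 and 51.2 with summits within 200 bp. It was 26.7, 24.4, 62.7 and 61.4 within 2500 bp and 11.6, 8.96, 47.7 and 46.2 with protein-coding genes only. Restricted peaks at or above the median fold gave 13.2 and 10.7, and equal list lengths gave 55.2 and 53.7 in shared peaks. The percent was lower in HT-restricted than in pSHF-restricted peaks in each of these settings. The ion handling mean passed the bound at -1.38 (stricter q), -0.66 (equal lengths), -0.67 (reciprocal), -0.83 (summits), -0.92 (50 kb), -0.86 (500 kb) and -0.94 (nearest end). The transcription factor mean passed it at -0.81 (summits), -1.01 (50 kb) and -0.98 (500 kb), and the atrial mean at -0.91 (500 kb). The Hedgehog mean fell inside the bounds at 0.25 (median fold), 0.19 (500 kb) and 0.11 (without *Gas1*), and the progenitor mean at 0.16 (median fold); the cause was not tested. Lists leaning to pSHF numbered 5 at the stricter q and 2 at the median fold, against 8. Lists leaning to HT numbered 4 at the stricter q, with summits and within 50 kb, 5 within 500 kb, and 1 over 1 kb from gene ends or by the median, against 2. The largest window excess was 5 for pSHF at the stricter q and at the median fold, and 8 for HT at the median fold. Of 59 named genes, the difference moved by over 1 peak (by more where it was large) without turning at 34 at the stricter q, 40 at the median fold, 13 by nearest gene end and 0 to 6 in the other settings, and 6 genes turned. It was 0 at the stricter q for *Skap1*, *Foxa2*, *Meox2*, *Rarg*, *Aldh1a1*, *Osr1*, *Ptch1* and *Hcn4*, and at the median fold for *Chd7*, *Gli3*, *Actc1*, *Meox2*, *Rarg*, *Hoxb3*, *Lgr5*, *Tbx5*, *Myl7* and *Hcn4*, among others. It was also 0 for *Actc1* without peaks near gene ends (from -4) and for *Wt1* with equal list lengths (from -3), while within 500 kb it rose to 8 for *Isl1* (from 0), 3 for *Osr1* (from 1), 9 for *Foxa2* (from 2) and 11 for *Foxf1* (from 6). The pSHF minus HT difference turned at the stricter q to -1 for *Gli2* and *Hoxb3* and -2 for *Rarb* and *Lgr5*. At *Hoxb3* this came from a shared HT peak whose pSHF partner fell below the cutoff. At the median fold the difference turned to 2 for *Gata4* and 1 for *Cdh5*, with the cutoff at 4.85 in pSHF and 5.49 in HT. Summit pileups of 5 to 147 reads in HT and 5 to 134 in pSHF limit what can be seen: sites with a few reads above background fall below the threshold by counting error alone.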

Other observations

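The gene families, their values without single genes, and the tests of coverage, of the strongest peaks and of gene length, were chosen after the data or their results were seen. Of 26 families picked by symbol, 5 leaned to the pSHF and 4 to the atria; no number due to chance applies, since several hold genes already named or in lists that leaned. Forkhead genes had 88 pSHF-restricted and 73 HT-restricted peaks over 44 genes (mean balance 0.24, percentile 99.98), and the 36 outside the fixed lists still lay at percentile 99.86. Sox genes had 45 and 31 (percentile 98.7), Wnt ligand genes 22 and 13 (99.8), and netrins with their receptors 42 and 26 (99.8), a family that includes *Unc5c* and lay at 99.0 without it. Semaphorin genes had 48 and 50 (97.8), or 96.9 without *Sema3d*, which is in the epicardial list. The more posterior Hox genes, groups 6 to 13, had only 4 and 8 restricted peaks over 24 genes (percentile 15.8). On the atrial side, the 29 genes whose symbols start with Prk, among them protein kinase A and C subunits, had 93 HT-restricted and 31 pSHF-restricted peaks (percentile 0.49), but this family was chosen after *Prkca* and *Prkce* had been seen and lay within the bounds without them (3.16). Myosin genes had 31 and 8 (percentile 0.58), but the 19 outside the fixed lists lay at percentile 31.4. Olfactory (46 and 27) and vomeronasal receptor genes (20 and 7) had means of -0.02 and -0.03, also past the bound. By the median instead of the mean, Wnt ligand genes were the family among these still past a bound (99.9), while the forkhead (58.1), Sox (65.9), netrin (84.7), semaphorin (80.9), Prk (14.9), myosin (52.7) and both receptor families (50) were not.

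The HT list held 22400 restricted peaks against 15132 for pSHF. With both lists cut to equal length the counts were 18427 and 16298, a smaller gap. Higher background coverage in HT is argued against, since the HT background pileup was 0.962 times that of pSHF. The background does not measure signal at open sites, where the median pSHF-to-HT pileup ratio was 0.8 at paired shared peaks. Sites open in both tissues that crossed the threshold in HT alone cannot be told apart from sites open in HT alone, because the spread between samples is unknown: 6.26% (5.60 to 6.97) of the 5000 strongest HT peaks were restricted, but the 0.00136% that counting error with scaled signal would give leaves that spread out. A difference between the tissues also stays open and was not tested. Whether blood cells gave the strong HT-restricted peaks cannot be told apart from other sources: 1.28% of the 313 (4 peaks) lay nearest one of 53 blood genes, but 0.319% (1 peak) lay nearest one of 58 cardiac genes, so gene lists of this size reach few of these peaks whatever their source.

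Erythroid genes leaned to the atria, and the beta-globin window had the largest HT excess of all 100-kb windows; *Hbb-bs* and *Hbb-bt*, the adult beta-globin genes in it, had 1 and 2 HT-restricted and 0 pSHF-restricted peaks. A candidate explanation is blood cells in the atrial pieces: a separate list of 16 erythroid genes, none in another list and chosen before its values were seen, lay at percentile 0.01 with 51 HT-restricted and 9 pSHF-restricted peaks. Whether other blood types shared the lean cannot be told apart. The macrophage list lay at percentile 71.1, with 5 pSHF-restricted and 4 HT-restricted peaks. But 8 of its 12 genes had no restricted peak, which the bound set in advance had not allowed for. Of the others, 3 leaned to HT and 1 to pSHF. The megakaryocyte list lay at 3.48 by the mean and 1.29 by the median, with 6 genes higher in HT and 1 in pSHF. Use of these genes by heart cells, such as the membrane skeleton gene *Ank1*, stays open, because expression was not measured here.

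The excess of pSHF-restricted peaks at *Lrmda* was 29 (33 against 4), but 3 at a −log10 q of at least 5 and 5 at or above the median fold enrichment, below *Errfi1* at 5 and 6. Extra copies of the region in pSHF can be neither shown nor excluded by the local background. At its pSHF peaks that background had a median of 1.09, or 0.73 times the 1.49 of all pSHF peaks. The ratio met the bound set against extra copies. But the 1.49 is no neutral level, since 65.6% of pSHF peaks were shared and 53.9% of those lay near gene ends. The 1.09 was above the genome-wide pSHF background of 0.857, but recovered local values could not fall below that level, so this comparison decides nothing. Gene length cannot be told apart from a cluster of sites: by nearest gene end the excess was 7, but that rule leaves out peaks over 100 kb from both ends of a gene. The peaks were typical weak ones, with a median fold enrichment of 4.31, equal to that of all pSHF-restricted peaks, so sites near the threshold stay open as a source of individual peaks. A regulatory region active in the pSHF may also account for the cluster and was not tested.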
